A study of Mus musculus with 8 samples.

How the data were processed

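RNA sequencing was used to measure gene expression in GFP-positive MLL-AF9 leukaemia cells that carried a doxycycline-inducible Klf4 transgene. The 8 libraries were grouped by the time point in the labels, 0h, 6h, 12h and 24h, with replicates 1 and 2 at each. Per the labels' protocols, total RNA was purified with an RNeasy kit and libraries were made with a TruSeq PE kit. The values are raw counts per Ensembl gene that the authors deposited, 1 file per library, without normalization. They were made with STAR, SAMtools 1.3 and HTSeq 2.0.3 on build mm10, per the submitters' processing notes. The version of STAR, the annotation release, the strand setting and any filter are not given in the sources used here. Reads of a gene and an overlapping or antisense gene are therefore not told apart with certainty, and genes with close copies may have lost reads.

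Each deposited count file held 47069 gene rows and 5 summary rows that name no gene. The summary rows were left out of library sizes and tests. Fragments counted to no gene feature made up 5.47%, 6.21%, 8.63% and 9.15% of all fragments on average at 0h, 6h, 12h and 24h. They may lie outside genes, in introns or antisense to genes, since the counting options are not given. Ambiguous fragments fell from 5.47% to 5.06%, and the other 3 summary rows held 0 counts. Gene names and coordinates came from GENCODE mouse release M21, which uses build mm10: 46574 gene IDs matched, and the 495 that did not held at most 0.0254% of a library's counts. Protein-coding genes took 98.9% of counts at 0h and 98.7% at 24h, and mitochondrially encoded genes 1.63% and 1.82%. No 2 libraries were identical. Totals ran from 20394546 to 26041347 gene counts per library. Intervals of 95% are exact binomial (Clopper-Pearson) for the Klf4 counts and for the ratio of Igf2, Wilson intervals for shares of calls, and exact Poisson limits for summed counts. The level that 0 counts allow was taken from 3 counts. The Wilson intervals treat called genes as independent, although they share the same 8 libraries, and may be too narrow. The other intervals and this level cover counting error only.

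Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by time point, which left 14263, and libraries were scaled by TMM. All 8 libraries entered 1 quasi-likelihood fit with a mean for each time point, which leaves 4 residual degrees of freedom. The biological coefficient of variation was 3.10% and the prior degrees of freedom 32.1. The comparisons were 6h, 12h and 24h with 0h, 12h with 6h and 24h with 12h, and an F test of the 3 differences from 0h covered the time course. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. The SE of a log2 fold change was taken as its absolute size divided by the square root of its F statistic. For large rises from few counts at 0h this SE is too narrow and can fall below counting error. CPM are per library scaled by TMM, except in the account of Klf4 per library, where the libraries' own totals were used in the plot. Gene groups were 38 lists fixed before the data were examined, tested with limma 3.58.1's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Lists with fewer than 5 tested members were not tested, which left out none. Some lists share members: 19 of 27 immediate early genes, 15 of 24 myeloid transcription factors and 16 of 22 reported KLF4 targets are also in another list.

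Genes were named by a rule fixed before the data were examined. It took Klf4, then for each comparison with 0h the 10 largest rises and 10 largest falls in log2 fold change among called genes with a mean of at least 3 on the log2 CPM scale over all libraries, or at least 4 at 1 time, whose libraries lay on the same side of both libraries of the other time. For 12h against 6h and 24h against 12h it took 5 each way. Predicted gene models were left out, and each list gave up to 4 members with the smallest adjusted p. A fold against 1 to 3 counts is given as a ratio with its 95% counting interval.

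The alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors, no filter and a stricter filter on low counts (a mean of at least 1 on the log2 CPM scale), a fit with the replicate number as a block, a fit of the 4 libraries of a comparison alone, a test against a fold of 1.5, leaving out each library in turn, and for lists camera with an estimated correlation and fry. Chosen after the data were seen were a GC and length correction, a second form of it that also centres the mean gene, and thinning to the smallest library. The first correction computed was the one that centres the mean gene. The form that keeps each library's level was added after its result was seen. GC and length were known for 14212 of 14263 tested genes. A library left alone at its time point in leave-one-out fits was assumed to vary like the other times.

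The pipeline was tested on simulated counts for 24h against 0h, with 13930 genes tested. It recovered 48% of genes changed 1.25-fold, 70% at 1.5-fold, 82% at 2-fold and 96% at 4-fold, with 5 false calls among 13707 unchanged genes. A list simulated at a fold of 1.3 was called by camera with the preset correlation, which also called 1 of the other 37 lists, with an estimated correlation, which called 0 others, and by fry, which called 4 others. Genes were drawn independently from the fitted dispersions. The simulation therefore does not test false calls where members of a list vary together or the dispersions are wrong. Tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. For the error that the shared 0h libraries bring to each comparison with 0h, all 8 libraries were drawn from the 0h means with the fitted dispersions, in 100 draws, a form chosen after the data were seen.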

Results

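RNA was sequenced from mouse leukaemia cells that carried MLL-AF9, a fusion oncogene that drives acute myeloid leukaemia, and a transgene from which doxycycline induces the transcription factor KLF4. GFP-positive leukaemia cells were sorted from leukaemic mice, and bone marrow is given as the tissue. The 8 libraries fell into 4 time points of 2 libraries each, 0h, 6h, 12h and 24h. The labels do not say from which event the hours count, and 0h served as the background of each comparison. Cells given doxycycline without the transgene were not analysed here. Gene counts came to 20394546 and 22467328 at 0h, 20944589 and 25706154 at 6h, 23489556 and 23416697 at 12h, and 26041347 and 24380981 at 24h. Between 18887 and 20599 genes had a count in a library. A gene with 0 counts could have stood at up to 0.115 to 0.147 CPM (counts scaled to the library total), depending on the library, a limit that covers counting error only. Replicates differed by more than sampling noise, with a chi-square per degree of freedom over genes of 1.86 at 0h, 3.93 at 6h, 1.99 at 12h and 3.01 at 24h. Nothing in the labels says that replicates came from separate mice, so the p-values measure only the spread between these libraries, which may be technical. On the first principal component, which held 59.7% of the variance, the libraries stood at -48.1 and -47.2 at 0h, -8.75 and -10.7 at 6h, 21.1 and 24.4 at 12h, and 34.2 and 35.0 at 24h.

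Klf4 is the induced gene, so its level in each library was examined first. Klf4 (ENSMUSG00000003032; build mm10, chromosome 4, 55527143 to 55532466, minus strand) encodes a zinc finger transcription factor. It stood at 3.57 ± 1.21 CPM at 0h (SD, n = 2), from 54 and 96 counts. Its level was 151 ± 0.474 CPM at 6h, 113 ± 2.74 CPM at 12h and 77.8 ± 1.34 CPM at 24h. The log2 fold changes against 0h were 5.39, 4.96 and 4.43, each with an SE of 0.09, and the adjusted p-values were 5.6e-34, 2.6e-32 and 2.6e-30. These and later SEs were derived from the F statistic, and are too narrow for large rises from few counts at 0h. Klf4 then fell by 0.43 ± 0.05 on the log2 scale (SE) from 6h to 12h and by 0.53 ± 0.05 from 12h to 24h, with adjusted p = 8.1e-08 and adjusted p = 2.8e-09. Neither of these falls passed a test against a fold of 1.5. Counts from the transgene and from the cells' own Klf4 are not separated in these values.

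**Figure D1:**
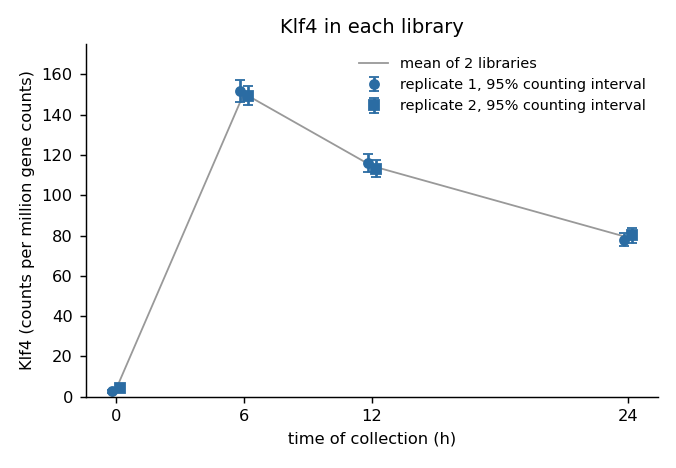
Klf4 in CPM of all gene counts (y axis) against the time of collection in hours (x axis), with 1 point per library, 95% counting intervals as bars and a line through the mean of the 2 libraries of each time. The 0h libraries stood at 2.65 and 4.27, and the 6h libraries at 152 and 149.

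The comparisons with 0h ask which genes differed from 0h at each later time. The loss of leukaemia cells, which the series names as its subject, was not measured in these files. Of 14263 genes tested, 2613 (18.3%) were called at 6h, 1389 higher and 1224 lower. At 12h 6229 genes (43.7%) were called, 3149 higher and 3080 lower. At 24h the count was 7257 (50.9%), with 3721 higher and 3536 lower. Most changes were small, with a median size on the log2 scale of 0.26, 0.31 and 0.36 among the called genes. Changes of at least 2-fold were mostly rises, 331 against 16 falls at 6h, 922 against 65 at 12h and 1115 against 151 at 24h. These numbers depended on the processing. A stricter filter on low counts gave 142 against 1, 305 against 10 and 371 against 42, and DESeq2 219 against 3, 682 against 24 and 865 against 101. The GC and length correction that centred the mean gene gave 303 against 29, 776 against 115 and 906 against 254. Without 0h replicate 1 or 0h replicate 2 the falls at 6h numbered 9 or 7. Tested against a fold of 1.5, 213, 600 and 953 genes were called. The balance of higher and lower calls depended on the scaling: with a GC and length correction 43.1% of the 6h calls were higher, against 53.2% without it. A form of that correction that also centred the mean gene gave 22.6%, 26.5% and 28.4% higher at 6h, 12h and 24h, against 53.2%, 50.6% and 51.3%, and placed the median gene at -0.07, -0.12 and -0.13 on the log2 scale. Both corrections were chosen after the data were seen. Fragments counted to no gene feature rose with time as well, from 5.47% ± 0.32 of all fragments at 0h (SD, n = 2) to 6.21% ± 0.56, 8.63% ± 0.45 and 9.15% ± 0.17.

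**Figure D2:**
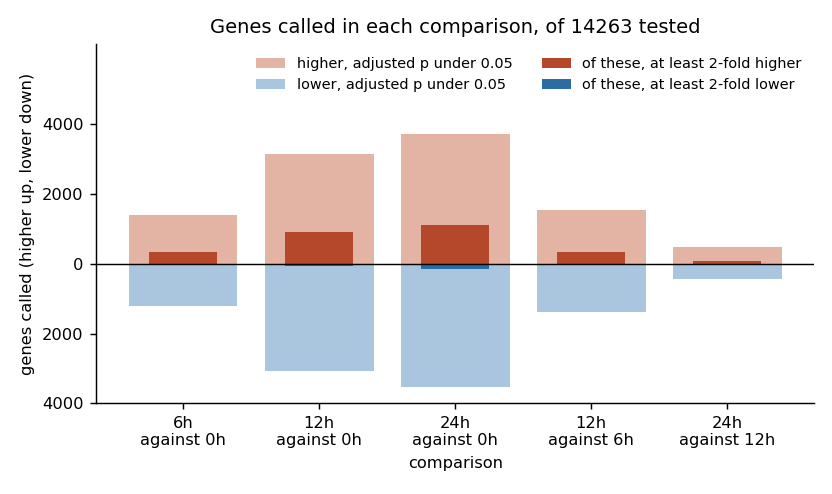
Number of genes called higher (up) and lower (down) in each comparison at an adjusted p under 0.05, with dark bars for the called genes that changed at least 2-fold. The 24h comparison with 0h has 3721 genes higher and 3536 lower, of which 1115 and 151 changed at least 2-fold.

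At 6h, genes that were close to silent at 0h had risen by many fold. Ahnak (chromosome 19, 8989284 to 9076914), which encodes a giant scaffold protein, rose from 1.23 ± 0.603 to 79.8 ± 4.99 CPM (SD, n = 2), a log2 fold change of 5.99 ± 0.12 (SE). The long noncoding RNA Miat (chromosome 5, 112213228 to 112229395) went from 0.230 ± 0.326 to 22.2 ± 3.82 CPM. Igf2 (chromosome 7, 142650766 to 142666816), the gene of an imprinted growth factor, had 1 count over both 0h libraries and 255 over both 6h libraries, a ratio of 229 with a 95% counting interval of 40.7 to 9074. The neuronal tubulin gene Tubb3 rose by 5.02 ± 0.23, Nrbp2 by 4.67 ± 0.20, and the calcium-binding S100a6 by 2.98 ± 0.17. Lsp1, an actin-binding protein of leukocytes, rose by 2.87 ± 0.17, the adhesion gene Amigo2 by 2.57 ± 0.13, and Klf3, a relative of Klf4, by 2.30 ± 0.08 (from 10.1 ± 0.292 to 49.9 ± 3.07 CPM). The falls named by the same rule were smaller. The chemokine gene Ccl3 fell by 0.73 ± 0.10, Milr1, an inhibitory receptor of mast cells, by 0.61 ± 0.06. The lipid enzyme genes Scd1 and Far2 fell by 0.58 ± 0.11 and 0.55 ± 0.06, and Dusp6, an ERK phosphatase, by 0.53 ± 0.10. Kcnj2, Clec2d, Bcas1, Gpr183 and Tsc22d1 fell by 0.62 ± 0.12, 0.54 ± 0.12, 0.54 ± 0.10, 0.52 ± 0.07 and 0.51 ± 0.09. Adjusted p-values of these genes ran from 5.6e-34 (Klf4) to 0.00068 (Clec2d). The 10 falls named here did not pass the test against a fold of 1.5.

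Genes of the integrated stress response, which the transcription factor ATF4 drives when amino acids are short or eIF2 is phosphorylated, rose together at 6h. Of this list 35 of 38 tested members were called higher, 0 lower and 3 in neither direction, or 35 and 0 when adjusted over the list alone (camera adjusted p = 2.4e-67, and adjusted p = 0.014 with an estimated correlation). The pseudokinase gene Trib3 rose by 2.08 ± 0.08, the cystine transporter gene Slc7a11 by 1.58 ± 0.09, and the metabolic enzyme genes Pck2 and Gpt2 by 0.79 ± 0.05 and 0.81 ± 0.05. Of the other KLF and SP family genes, 8 of 14 tested members were called higher, 0 lower and 6 in neither direction, or 8 and 1 when adjusted over the list alone (camera adjusted p = 4.1e-13, and adjusted p = 0.049 with an estimated correlation). Klf13 rose by 0.79 ± 0.05, Klf10 by 0.98 ± 0.08 and Klf8 by 2.30 ± 0.23. Cholesterol synthesis genes and SREBP2 targets fell: 0 higher, 20 lower and 5 not called of 25, or 0 and 22 adjusted over the list alone (camera adjusted p = 6.6e-16, and adjusted p = 0.014 with an estimated correlation). Insig1 fell by 0.48 ± 0.04, Acat2 by 0.46 ± 0.05, Hmgcs1 by 0.42 ± 0.05 and Cyp51 by 0.39 ± 0.05. Genes of the unfolded protein response of the endoplasmic reticulum (ER) went mostly the other way from the ATF4 list, with 1 higher, 17 lower and 8 not called of 26, or 1 and 17 adjusted over the list alone (camera adjusted p = 3.5e-10, and adjusted p = 0.029 with an estimated correlation). Its chaperone genes Hspa5, Sdf2l1 and Calr fell by 0.42 ± 0.04, 0.46 ± 0.05 and 0.34 ± 0.04, while Herpud1, a gene of ER-associated degradation, rose by 0.49 ± 0.05.

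Lists of housekeeping complexes fell slightly at 6h by the preset camera test, none of them with an estimated correlation. More of their members were lower when the mean gene was centred, for MYC targets 36 of 55 and for the mitochondrial ribosome 27 of 45. Of the cytosolic ribosomal proteins 34 of 52 were lower and 0 higher (43 lower adjusted over the list alone; median log2 fold change -0.15; camera adjusted p = 1.8e-11, and adjusted p = 0.49 with an estimated correlation, and fry adjusted p = 0.10). Nuclear oxidative phosphorylation genes had 20 of 43 lower (28 adjusted over the list alone; camera adjusted p = 2.5e-08, and adjusted p = 0.49 with an estimated correlation, and fry adjusted p = 0.085). The mitochondrial ribosome had 15 of 45 lower (20 adjusted over the list alone; camera adjusted p = 8.9e-07, and adjusted p = 0.29 with an estimated correlation). For heat shock genes and chaperones the counts were 1 higher, 12 lower and 10 not called of 23, or 1 and 15 adjusted over the list alone (camera adjusted p = 1.0e-05, and adjusted p = 0.26 with an estimated correlation). Hspa8 fell by 0.41 ± 0.04 and Hsph1 by 0.37 ± 0.04. MYC targets and ribosome biogenesis genes had 11 of 55 lower and 44 not called (12 lower adjusted over the list alone; camera adjusted p = 0.00017, and adjusted p = 0.29 with an estimated correlation). Among the falls were Nhp2 (-0.27) and Fbl (-0.24). The adhesion list was called higher (8 higher, 4 lower and 13 not called of 25, or 9 and 4 adjusted over the list alone; camera adjusted p = 0.0048, and adjusted p = 0.17 with an estimated correlation). Itgb7 rose by 1.22 ± 0.05 and Itga5 by 0.55 ± 0.05. The list's median of 0.02 turned negative with the GC and length correction that centred the mean gene (6 higher and 7 lower), and its adjusted p was 0.078 with no filter on low counts.

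Gene calls at 6h, 12h and 24h against 0h came from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, and list calls from camera. At 6h DESeq2 called 1668 genes, and the count was 1702 without 0h replicate 1 and 1319 without 0h replicate 2.

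Of the 1389 genes higher at 6h, 466 were called further up from 6h to 12h and 44 back down, and other genes were first called at 12h. Ahnak stood at 92.9 ± 0.451 CPM (SD, n = 2), Miat at 51.3 ± 5.98 CPM, Igf2 at 14.9 ± 1.59 CPM, Lsp1 at 24.3 ± 1.16 CPM and S100a6 at 20.9 ± 0.427 CPM. Nrbp2 was higher than at 0h by 5.45 ± 0.18 (SE) on the log2 scale and Tubb3 by 5.30 ± 0.22. The immediate early transcription factor genes Egr1 (chromosome 18, 34859823 to 34864984) and Jun (chromosome 4, 95049034 to 95052222) joined them. Egr1 went from 0.461 ± 0.130 to 17.4 ± 1.61 CPM (log2 fold change 5.23 ± 0.21) and Jun from 1.44 ± 0.183 to 20.9 ± 0.847 CPM (3.85 ± 0.15). Among the falls, Ms4a3 (chromosome 19, 11629496 to 11640851), a gene of granulocyte and monocyte progenitors, went from 138 ± 0.676 to 70.8 ± 2.60 CPM, 1.95-fold lower. The oxysterol receptor gene Gpr183 fell by 0.90 ± 0.07, the cytokine receptor gene Il21r by 0.77 ± 0.08, and the cytokine gene Tnfsf14 by 0.76 ± 0.09. Dnmt3l, a cofactor of DNA methyltransferases, fell by 0.76 ± 0.08, the protease inhibitor gene Serpina3g by 0.75 ± 0.08 and the glutamate receptor gene Gria3 by 0.74 ± 0.09. Zbtb26 fell by 0.82 ± 0.14 and Pyurf by 0.80 ± 0.12. The small nuclear RNA gene Rn7sk was called at -0.96 ± 0.23, but its 12h libraries were far apart (6.99 ± 5.99 CPM) and the call rested on 1 of them. Without 12h replicate 2 the value was -0.27 (adjusted p = 0.10), and DESeq2 gave adjusted p = 0.29. The other named genes had adjusted p-values from 2.6e-32 (Ahnak) to 7.9e-06 (Zbtb26), and of the falls only those of Ms4a3 and Gpr183 passed the test against a fold of 1.5.

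The ATF4 list was higher almost throughout at 12h, with 37 higher, 0 lower and 1 not called of 38, or 38 and 0 adjusted over the list alone (camera adjusted p = 6.1e-63, and adjusted p = 0.017 with an estimated correlation). Trib3 had risen by 2.49 ± 0.08, Slc7a11 by 1.97 ± 0.09 and Pck2 by 1.21 ± 0.05. The KLF family had 11 higher, 0 lower and 3 not called of 14, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.9e-13, and adjusted p = 0.048 with an estimated correlation). Klf3 rose by 2.70 ± 0.08 and Klf2 by 1.60 ± 0.12. Immediate early genes, which cells also switch on when tissue is dissociated, were higher as a list: 17 higher, 2 lower and 5 not called of 24, or 17 and 2 adjusted over the list alone (camera adjusted p = 3.6e-13, and adjusted p = 0.021 with an estimated correlation). Beside Egr1 and Jun, Zfp36 rose by 0.96 ± 0.07 and Ier2 by 0.94 ± 0.05. Genes of the ER unfolded protein response remained mostly lower (4 higher, 19 lower and 3 not called of 26, or 4 and 19 adjusted over the list alone; camera adjusted p = 1.4e-08, and adjusted p = 0.039 with an estimated correlation). Calr stood at -0.65 ± 0.04 and Hspa5 at -0.60 ± 0.04. MYC targets and ribosome biogenesis genes were lower in 52 of 55 tested members and higher in 0 (52 lower adjusted over the list alone; median -0.29; camera adjusted p = 3.8e-19, and adjusted p = 0.057 with an estimated correlation), among them Nop16 (-0.51), Fbl (-0.46) and Bop1 (-0.44).

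Mitotic genes were higher at 12h (37 higher, 3 lower and 26 not called of 66, or 38 and 3 adjusted over the list alone; camera adjusted p = 0.00016, and adjusted p = 0.18 with an estimated correlation), and 23 were higher and 13 lower with the GC and length correction that centred the mean gene. Cenpe rose by 0.50 ± 0.05 and Mki67, the gene of the Ki-67 proliferation antigen, by 0.46 ± 0.04. Stem and progenitor genes leaned lower (2 higher, 8 lower and 4 not called of 14, or 2 and 8 adjusted over the list alone; camera adjusted p = 0.0069, and adjusted p = 0.15 with an estimated correlation). Cd34 fell by 0.70 ± 0.04 and Kit by 0.35 ± 0.05. Genes of mast cells and basophils, a list that shares Kit, moved the same way (0 higher, 6 lower and 2 not called of 8, or 0 and 6 adjusted over the list alone; camera adjusted p = 0.029, and adjusted p = 0.17 with an estimated correlation). That mast cell and basophil call was lost without 0h replicate 2, 6h replicate 2 or 12h replicate 1 (adjusted p from 0.051 to 0.064). The myeloid transcription factor list was called higher (12 higher, 4 lower and 6 not called of 22, or 12 and 4 adjusted over the list alone; camera adjusted p = 0.00029, and adjusted p = 0.15 with an estimated correlation). With the GC and length correction 11 of its members were higher and 8 lower, and 9 and 9 with the form that centred the mean gene. Its leading members were Jun and Egr1, which the immediate early list also holds, while Tfec fell by 0.68 ± 0.05. Cytosolic ribosomal proteins (44 of 52 lower, 44 adjusted over the list alone), mitochondrial ribosome (38 of 45, 42), nuclear oxidative phosphorylation (36 of 43, 38) and heat shock genes (17 of 23, 17) were lower by the preset test, with adjusted p = 0.46, 0.17, 0.41 and 0.17 with an estimated correlation.

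At 24h Igf2 reached 20.8 ± 0.210 CPM (SD, n = 2), Miat 57.2 ± 0.262 CPM and Lsp1 43.5 ± 0.448 CPM. Ahnak was higher than at 0h by 6.24 ± 0.11 on the log2 scale (SE), and Egr1 and Jun stood higher by 5.67 ± 0.19 and 4.14 ± 0.14. S100a6 was up by 4.21 ± 0.14, Nrbp2 by 4.95 ± 0.19 and Tubb3 by 4.23 ± 0.25. Falls were larger than before. C2cd4a fell from 18.4 ± 1.58 to 6.84 ± 0.0196 CPM, 2.69-fold lower, and Chga, the gene of chromogranin A, by 1.36 ± 0.08 on the log2 scale. The basophil protease gene Mcpt8 fell by 1.26 ± 0.11, Milr1 by 1.24 ± 0.06, Serpina3g by 1.23 ± 0.09, Gpr183 by 1.22 ± 0.08, Afp, the alpha-fetoprotein gene, by 1.08 ± 0.08 and Ms4a3 by 0.99 ± 0.05. Slpi, a gene of a secreted protease inhibitor, went from 112 ± 0.0168 to 56.2 ± 5.89 CPM. Cd34 (chromosome 1, 194938819 to 194961279), a surface marker of haematopoietic progenitors, went from 243 ± 1.55 to 116 ± 1.33 CPM, 2.10-fold lower (adjusted p = 5.7e-22). Adjusted p-values of the genes named at 24h ran from 3.5e-32 (Ahnak) to 2.5e-12 (Mcpt8). Each of the genes named at 24h kept its call under every alternative tried, the test against a fold of 1.5 included.

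**Figure D3:**
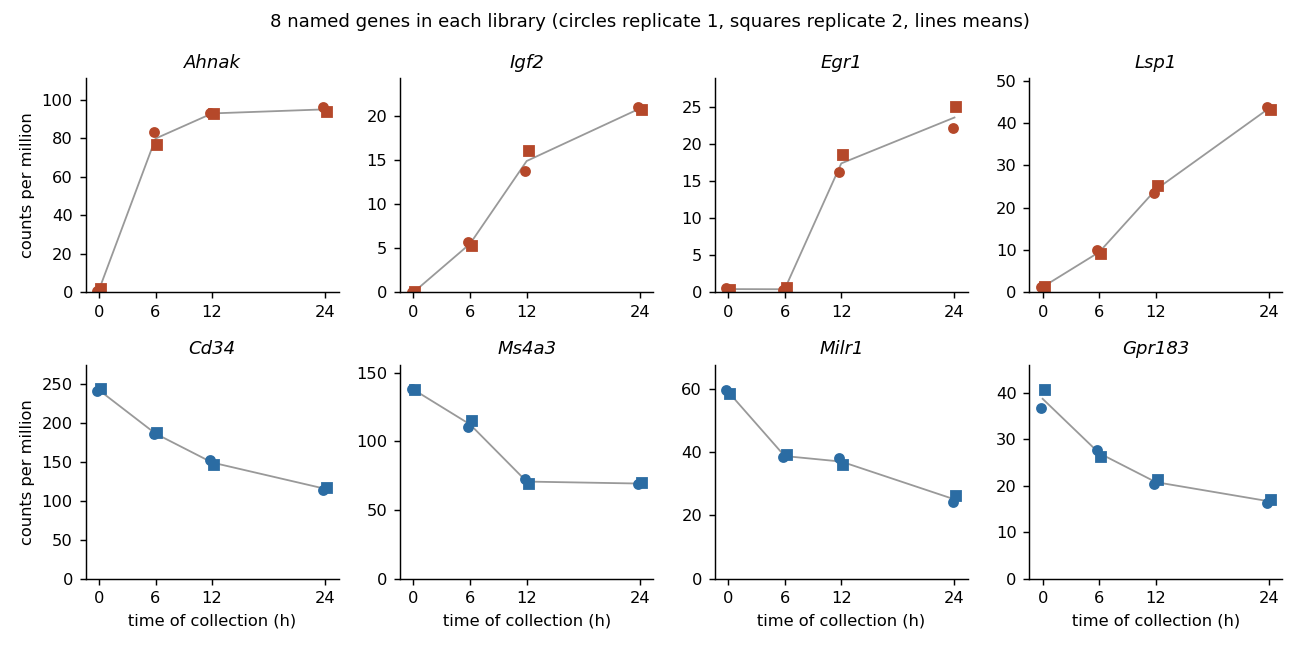
CPM (y axes, each from 0) against the time of collection in hours (x axes) for Ahnak, Igf2, Egr1, Lsp1, Cd34, Ms4a3, Milr1 and Gpr183, with 1 point per library and lines through the means of 2 libraries. Cd34 went down from a mean of 243 at 0h to 116 at 24h, and Egr1 stood at 0.461 at 0h, 17.4 at 12h and 23.5 at 24h.

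All tested members of the ATF4 list were called higher at 24h, 38 of 38, and 38 when adjusted over the list alone (median log2 fold change 0.91; camera adjusted p = 1.8e-99, and adjusted p = 0.0066 with an estimated correlation). Cth, which makes cysteine from cystathionine, rose by 3.38 ± 0.08, Trib3 by 3.25 ± 0.07, Pck2 by 1.63 ± 0.05 and Gpt2 by 1.62 ± 0.05. ER unfolded protein response genes were still mostly lower (4 higher, 18 lower and 4 not called of 26, or 4 and 18 adjusted over the list alone; camera adjusted p = 6.4e-09, and adjusted p = 0.038 with an estimated correlation). Calr fell by 0.84 ± 0.04 and Sdf2l1 by 0.82 ± 0.05. Immediate early genes remained higher as a list (16 higher, 1 lower and 7 not called of 24, or 16 and 1 adjusted over the list alone; camera adjusted p = 6.8e-12, and adjusted p = 0.024 with an estimated correlation). So did the KLF family by the preset test (12 higher, 0 lower and 2 not called of 14, or 12 and 0 adjusted over the list alone; camera adjusted p = 1.6e-09, and adjusted p = 0.090 with an estimated correlation). TGF-beta and SMAD targets were called higher (12 higher, 1 lower and 8 not called of 21, or 12 and 1 adjusted over the list alone; camera adjusted p = 0.00067, and adjusted p = 0.11 with an estimated correlation). With the GC and length correction that centred the mean gene 10 were higher and 5 lower. Thbs1 rose by 0.82 ± 0.05 and Tgfbi by 3.22 ± 0.28. MYC targets and ribosome biogenesis genes had 45 of 55 lower and 2 higher (48 lower adjusted over the list alone; camera adjusted p = 5.5e-11, and adjusted p = 0.11 with an estimated correlation).

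Stem and progenitor genes were lower at 24h (2 higher, 8 lower and 4 not called of 14, or 2 and 8 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.11 with an estimated correlation). Angpt1 fell by 0.61 ± 0.06, Lmo2 by 0.34 ± 0.04 and Erg by 0.36 ± 0.05 beside Cd34. Mast cell and basophil genes fell with them (0 higher, 5 lower and 3 not called of 8, or 0 and 5 adjusted over the list alone; camera adjusted p = 0.0029, and adjusted p = 0.11 with an estimated correlation). Hdc, the histidine decarboxylase gene, fell by 0.70 ± 0.05 and Cpa3 by 0.58 ± 0.07. The p53 target list was called lower (6 higher, 16 lower and 10 not called of 32, or 6 and 17 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.12 with an estimated correlation). Ccng1 stood at -0.64 ± 0.04 and Bax, a promoter of apoptosis, at -0.58 ± 0.05, while Sesn2, which ATF4 also drives, rose by 0.93 ± 0.05. Histone genes were called higher (12 higher, 3 lower and 8 not called of 23, or 12 and 3 adjusted over the list alone; camera adjusted p = 0.040, and adjusted p = 0.18 with an estimated correlation), led by H2afx (0.94 ± 0.05) and the linker histone gene Hist1h1c (1.21 ± 0.08). The histone call was lost without 0h replicate 1, either 6h replicate or 24h replicate 1 (adjusted p from 0.056 to 0.073). The adhesion list was called higher (11 higher, 9 lower and 5 not called of 25, or 11 and 9 adjusted over the list alone; camera adjusted p = 0.0049, and adjusted p = 0.11 with an estimated correlation). Itgb7 rose by 2.27 ± 0.05 and Itgal by 0.69 ± 0.04. Its median was -0.01 and changed sign with the GC and length correction, the centring form gave 10 higher and 13 lower, and its adjusted p was 0.40 with no filter on low counts. Myeloid transcription factors were higher (11 higher, 4 lower and 7 not called of 22, or 11 and 4 adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.13 with an estimated correlation), again led by Egr1 and Jun. The GC and length correction gave 11 higher and 8 lower, and the form that centred the mean gene 8 and 9, with the median going from 0.32 to 0.20 and 0.07. Cytosolic ribosomal proteins (39 of 52 lower, 41 adjusted over the list alone, and fry adjusted p = 0.052), mitochondrial ribosome (36 of 45, 36), nuclear oxidative phosphorylation (38 of 43, 40) and heat shock genes (17 of 23, 17) were lower by the preset test, with adjusted p = 0.54, 0.23, 0.39 and 0.18 with an estimated correlation.

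**Figure D4:**
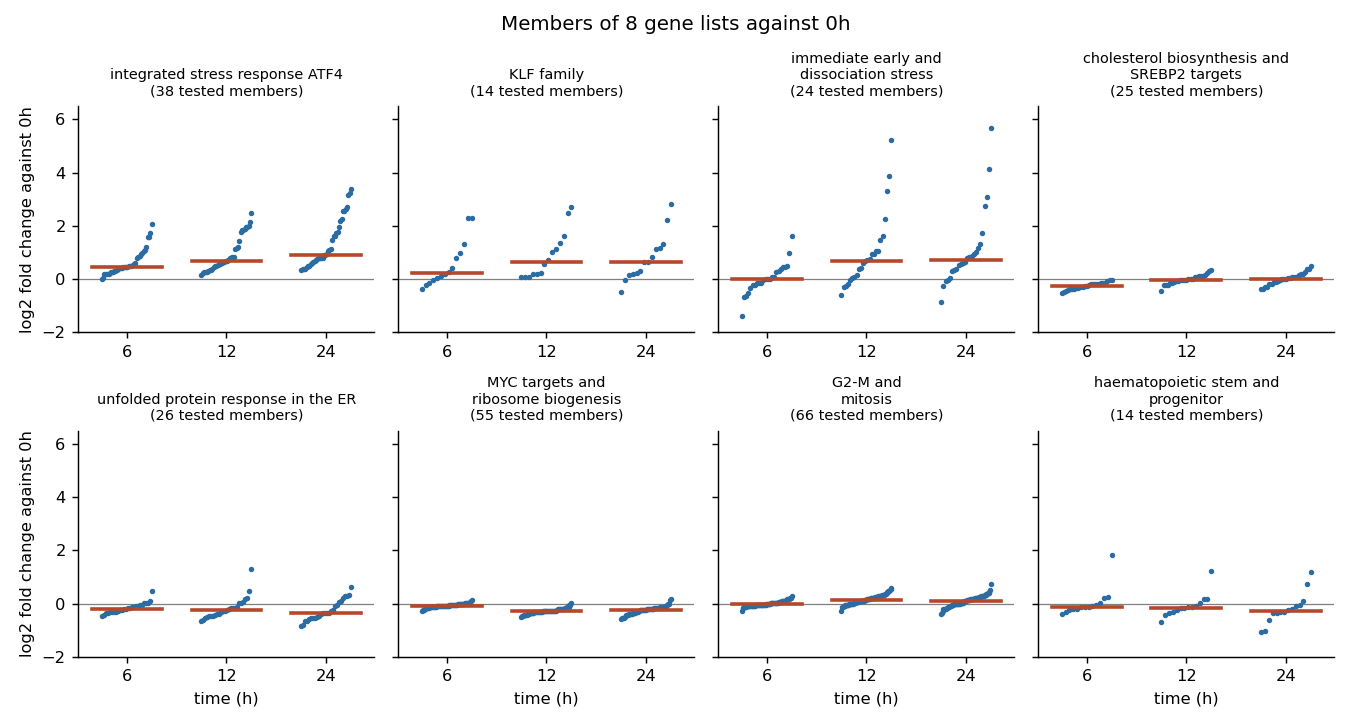
Log2 fold change against 0h (y axes) of each tested member of 8 gene lists at 6h, 12h and 24h (x axes), with members in rising order as points and the list's median as a bar. The ATF4 list has medians of 0.46, 0.67 and 0.91, and the median of the mitotic list at 24h (0.10) changes sign with the GC and length correction that centres the mean gene.

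A further 5 lists were not called at 24h. Genes reported elsewhere as KLF4 targets went both ways (4 higher, 4 lower and 10 not called of 18, or 4 and 4 adjusted over the list alone; camera adjusted p = 0.48). Their median of -0.02 changed sign with the GC and length correction. The transferrin receptor gene Tfrc fell by 0.69 ± 0.04, Trp53 by 0.25 ± 0.04, and Ccnd2 and Itgam rose by 0.42 ± 0.06 and 0.36 ± 0.06. The MLL-AF9 and HOXA-MEIS1 programme had 7 higher, 8 lower and 7 not called of 22, or 7 and 8 adjusted over the list alone (camera adjusted p = 0.30). Eya1 fell by 0.46 ± 0.05, Mef2c down by 0.62 ± 0.07 and Hoxa3 up by 0.50 ± 0.07. Apoptosis and BCL2 family genes also went both ways (9 higher, 7 lower and 20 not called of 36, or 9 and 7 adjusted over the list alone; camera adjusted p = 0.69), around a median of 0.02 that changed sign with the correction that centred the mean gene. Casp8 fell by 0.38 ± 0.04 while Bnip3 rose by 0.73 ± 0.07. Monocyte and macrophage genes (15 higher, 9 lower and 2 not called of 26, or 15 and 9 adjusted over the list alone; camera adjusted p = 0.20) included a rise of Nr4a1 by 1.71 ± 0.13 and falls of the Fc receptor gene Fcgr3 by 0.61 ± 0.04 and of Adgre1 by 0.70 ± 0.06. In the neutrophil and granule list (13 higher, 7 lower and 4 not called of 24, or 13 and 7 adjusted over the list alone; camera adjusted p = 0.10), Ly6g, which encodes a neutrophil surface marker, rose by 3.43 ± 0.11, and Prtn3, the gene of proteinase 3, fell by 0.50 ± 0.05. The balance within these 5 lists depended on the scaling. Centring the mean gene as above gave 3 higher and 8 lower for the KLF4 targets, 4 and 14 for the MLL-AF9 programme, 7 and 13 for apoptosis, 11 and 11 for monocytes and macrophages, and 10 and 8 for neutrophils and granules.

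The comparison of 12h with 6h asks what changed after the first response. Egr1 went from 0.438 ± 0.215 to 17.4 ± 1.61 CPM (SD, n = 2), a log2 fold change of 5.25 ± 0.20 (SE), and Jun rose by 2.90 ± 0.13. Ly6g rose by 1.80 ± 0.11, Klf2, a KLF gene that is also an immediate early gene, by 1.75 ± 0.12, and Igf2 by 1.43 ± 0.12. Ms4a3 fell by 0.67 ± 0.05, Tcta by 0.62 ± 0.12 and the transcription factor gene Sox13 by 0.60 ± 0.13, while Zbtb26 went from 11.7 ± 2.14 to 5.76 ± 0.357 CPM. Their adjusted p-values and those of the rises ran from 6.2e-21 (Egr1) to 0.0010 (Sox13). The falls of Ms4a3, Zbtb26, Tcta and Sox13 did not pass the test against a fold of 1.5. Rn7sk was called at -1.02 ± 0.22, but without 12h replicate 2 its adjusted p was 0.093, and DESeq2 gave 0.36. Of the immediate early list, 15 higher, 1 lower and 8 not called of 24, or 17 and 1 adjusted over the list alone (camera adjusted p = 4.7e-34, and adjusted p = 0.0060 with an estimated correlation). Cholesterol synthesis genes, which had fallen by 6h, rose again: 18 higher, 1 lower and 6 not called of 25, or 18 and 1 adjusted over the list alone (camera adjusted p = 4.2e-17, and adjusted p = 0.012 with an estimated correlation). Fdft1 rose by 0.66 ± 0.06, Mvd by 0.56 ± 0.06 and Insig1 by 0.40 ± 0.04. The earlier fall of this list and its rise here both rest on the same 6h libraries. MYC targets and ribosome biogenesis genes fell in 46 of 55 (51 adjusted over the list alone; camera adjusted p = 1.1e-27, and adjusted p = 0.042 with an estimated correlation). Ncl fell by 0.33 ± 0.04 and Utp20 by 0.33 ± 0.04. The ATF4 list rose further (25 higher, 0 lower and 13 not called of 38, or 27 and 0 adjusted over the list alone; camera adjusted p = 6.6e-20, and adjusted p = 0.054 with an estimated correlation). Ppp1r15a, which restores translation after eIF2 phosphorylation, rose by 1.41 ± 0.10 and Chac1 by 0.94 ± 0.07. Mitotic genes (37 higher, 0 lower and 29 not called of 66, or 44 and 0 adjusted over the list alone; camera adjusted p = 1.9e-13, and adjusted p = 0.054 with an estimated correlation) and histone genes (7 higher, 0 lower and 16 not called of 23, or 8 and 0 adjusted over the list alone; camera adjusted p = 0.00023, and adjusted p = 0.054 with an estimated correlation) were called higher, with Kif23 up by 0.41 ± 0.05 and Hist1h1c by 1.04 ± 0.09. The KLF family was called higher too (5 higher, 0 lower and 9 not called of 14, or 5 and 0 adjusted over the list alone; camera adjusted p = 1.5e-05, and adjusted p = 0.12 with an estimated correlation).

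In all, 2947 genes were called at 12h against 6h by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, 1551 higher and 1396 lower, with 333 and 30 of at least 2-fold. The share higher was 52.6%, and 28.9% with the GC and length correction that centred the mean gene. DESeq2 called 1632 genes, the test against a fold of 1.5 called 85, and leaving out 12h replicate 1 or 12h replicate 2 left 1853 or 1296. The 2-fold rises and falls numbered 69 and 4 with a stricter filter on low counts, 141 and 4 by DESeq2, 304 and 57 with the correction that centred the mean gene, and 191 and 21 without 12h replicate 2.

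The comparison of 24h with 12h asks whether the response was still moving after 12h. Cth rose from 25.8 ± 0.392 to 67.8 ± 1.33 CPM (SD, n = 2; log2 fold change 1.39 ± 0.07, SE), the arginine transporter gene Slc7a3 by 1.31 ± 0.09, and Thbs1, the thrombospondin 1 gene, by 1.16 ± 0.05. The lipoprotein receptor gene Vldlr rose by 1.09 ± 0.07 and Extl1 by 1.05 ± 0.09. Tubb3 fell by 1.07 ± 0.12, Mcpt8 by 0.82 ± 0.11, C2cd4a by 0.79 ± 0.11, Chga by 0.75 ± 0.08 and the inhibitory receptor gene Btla by 0.65 ± 0.07. Adjusted p-values of these genes ran from 2.4e-19 (Thbs1) to 5.6e-06 (C2cd4a), and of the 5 falls only that of Tubb3 passed the test against a fold of 1.5. The ATF4 list rose again, with 31 higher, 0 lower and 7 not called of 38, or 35 and 0 adjusted over the list alone (camera adjusted p = 4.0e-82, and adjusted p = 0.017 with an estimated correlation). Genes of G1-S and DNA replication fell slightly: 0 higher, 18 lower and 41 not called of 59, or 0 and 35 adjusted over the list alone (camera adjusted p = 2.2e-14, and adjusted p = 0.035 with an estimated correlation). Lig1, a DNA ligase gene, fell by 0.21 ± 0.04 and Uhrf1 by 0.19 ± 0.04. The Uhrf1 call was lost without 12h replicate 2 (adjusted p = 0.12) or 24h replicate 2 (adjusted p = 0.068). Mitotic genes were called lower (0 higher, 6 lower and 60 not called of 66, or 0 and 6 adjusted over the list alone; camera adjusted p = 0.00016, and adjusted p = 0.20 with an estimated correlation). Neutrophil and granule genes (10 higher, 0 lower and 14 not called of 24, or 12 and 1 adjusted over the list alone; camera adjusted p = 4.1e-09, and adjusted p = 0.098 with an estimated correlation) were called higher, with Ly6g up by 1.04 ± 0.08, Ngp by 0.45 ± 0.06 and Mpo, the myeloperoxidase gene, by 0.38 ± 0.06. Monocyte and macrophage genes (11 higher, 3 lower and 12 not called of 26, or 12 and 4 adjusted over the list alone; camera adjusted p = 0.00018, and adjusted p = 0.098 with an estimated correlation) were called higher as well, with the fibronectin gene Fn1 up by 3.98 ± 0.45 and Ly6c2 by 0.31 ± 0.04. Glycolysis genes were called higher (9 higher, 1 lower and 16 not called of 26, or 15 and 1 adjusted over the list alone; camera adjusted p = 1.1e-06, and adjusted p = 0.23 with an estimated correlation). Vegfa rose by 0.52 ± 0.05 and Pdk1 by 0.31 ± 0.06. The glycolysis list had been called lower at 6h against 0h (3 higher, 9 lower and 14 not called of 26, or 3 and 12 adjusted over the list alone; camera adjusted p = 0.020, and adjusted p = 0.52 with an estimated correlation, and fry adjusted p = 0.085). That call was lost without 0h replicate 2 (adjusted p = 0.12) and without 6h replicate 1 (adjusted p = 0.083). At 24h against 0h the list was not called (9 higher, 8 lower and 9 not called of 26, or 9 and 9 adjusted over the list alone; camera adjusted p = 0.74), and its median of 0.015 changed sign with either GC and length correction, with 6 higher and 16 lower under the centring form (2 and 16 at 6h). The mast cell and basophil list was called lower (0 higher, 3 lower and 5 not called of 8, or 1 and 3 adjusted over the list alone; camera adjusted p = 0.0092, and adjusted p = 0.20 with an estimated correlation). It was not called without 24h replicate 1 (adjusted p = 0.11) and with no filter on low counts (adjusted p = 0.065).

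In this comparison 921 genes were called by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, 487 higher and 434 lower, with 69 and 22 of at least 2-fold. The share higher was 52.9%, against 41.4% with no filter on low counts and 39.1% with the GC and length correction that centred the mean gene. DESeq2 called 445 genes, the test against a fold of 1.5 called 41, and the counts were 373, 386 and 449 without 12h replicate 1, 12h replicate 2 and 24h replicate 2. For the 2-fold rises and falls a stricter filter on low counts gave 18 and 7, and DESeq2 22 and 6. They came to 45 and 17 without 12h replicate 1, 49 and 6 without 12h replicate 2, and 50 and 12 without 24h replicate 1.

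Over the whole time course, the F test of the 3 differences from 0h together called 7532 of 14263 genes (52.8%). Called genes recurred: 2213 genes were called the same way at 6h, 12h and 24h, 1178 higher and 1035 lower. Independent lists of the same sizes would share 145.5, and libraries simulated without change gave 0, which says little, since they shared 0 calls at any pair of times as well. The fold changes at 6h and 24h correlated at 0.78, with a covariance of 0.41. Libraries simulated without change, those of 0h included, gave 0.55 and 0.055 on average in 100 draws, through the shared 0h libraries. Splitting the 0h libraries would leave 1 in each part, so part of the excess may come from the shared controls. The recurring count was 1456 by DESeq2, 1156 without 0h replicate 2 and 3474 with the GC and length correction that centred the mean gene. Of the 1389 genes higher at 6h, 1232 (88.7%) were also called higher at 24h and 5 lower, and of the 1224 lower at 6h, 1104 (90.2%) were also called lower at 24h and 16 higher. Of 38 gene lists, camera with the preset correlation called 14, 17 and 16 at 6h, 12h and 24h against 0h, 18 at 12h against 6h and 15 at 24h against 12h. With an estimated correlation 4, 4, 3, 3 and 2 were called, all of them among the former. The list's median and the camera test differed in sign for 6, 5, 5, 2 and 6 lists, of which the adhesion list at 24h and the MAPK and RAS feedback list at 12h (median -0.02) were called. The lists called with an estimated correlation were the ATF4 list at each comparison except 12h against 6h, the ER unfolded protein response at the 3 comparisons with 0h, the KLF family at 6h and 12h and cholesterol synthesis at 6h and at 12h against 6h. The others were immediate early genes at 12h, 24h and 12h against 6h, MYC targets at 12h against 6h, and G1-S genes at 24h against 12h. Genes that overlap another gene, lie antisense to one or have close paralogs, such as the histone, ribosomal protein and Ly6 genes, remain uncertain, since the strand setting of the counting is not given.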

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

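The tests of the ATF4 list, of T and NK cell genes and of the 2-fold rises under a GC and length correction were chosen after their results were seen, and the other tests of the 2-fold rises before.

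Fragments counted to no gene feature, which no comparison used, stood above the 0h libraries at each later time. Their means were 6.21% at 6h, 8.63% at 12h and 9.15% at 24h, against at most 5.70% in a 0h library. Several named genes later moved against their first change, in a test of the later step itself. Both tests use the libraries of the time in between, so a deviation of those libraries alone could give a change and its return. The same holds for the gene lists below. From 6h to 12h Ccl3 rose by 0.86 on the log2 scale after a change of -0.73 from 0h, Scd1 by 1.14 after -0.58 and Bcas1 by 0.42 after -0.54. Klf4 moved by -0.43 after 5.39. From 12h to 24h Klf4 moved by -0.53 after 4.96, Tubb3 by -1.07 after 5.30, Nrbp2 by -0.50 after 5.45 and Scd1 by -0.49 after 0.56. Thbs1 moved by 1.16 after -0.34. Rn7sk moved by 0.96 after -0.96, with 11.2 and 2.76 CPM in the 12h libraries, and without 12h replicate 2 its change from 6h to 12h was -0.33. In all, 38 of 47 named genes differed between 6h and 12h and 28 between 12h and 24h, and 10 of these steps went back. The named genes were picked for large changes, some of them in these same steps, so high numbers follow from the choice. Of all 14263 tested genes, 20.7% and 6.46% were called in these 2 steps. Of the 38 lists, 18 and 15 differed, and 3 went back. Cholesterol synthesis turned to a median of 0.29 from 6h to 12h after -0.25. Mitotic genes turned to -0.056 from 12h to 24h after 0.15, not called with an estimated correlation (adjusted p = 0.20). MYC targets and ribosome biogenesis turned to 0.060 from 12h to 24h after -0.29, with 4 of 55 members called. The call of this list had adjusted p = 0.040, which ranged from 0.031 to 0.53 over the alternatives. It was lost with DESeq2 size factors (0.071), without 12h replicate 2 (0.13), without 24h replicate 1 (0.059), without 24h replicate 2 (0.082), with fry (0.083) and with an estimated correlation (0.53).

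The ATF4 list rose at each time against 0h while the chaperones of the ER did not. A scaling error would move unrelated genes alike, so it could not by itself set this list apart from the ER list. It could still shift the level of both. With the GC and length correction that centres the mean gene 37 of 38 tested members were still higher at 24h. DESeq2 size factors, which hardly moved the scale, gave 38. That correction placed the median gene at -0.13, a small shift beside the list's median of 0.91, so it could not decide this. A full unfolded protein response would raise the ER list too, but its median was -0.35 at 24h, so the tables argue against that as the whole cause. Doxycycline itself, which acts on mitochondrial translation, may raise ATF4 targets, and with 0 libraries of treated cells without the transgene it cannot be told apart from KLF4. An effect of KLF4 stays open as a hypothesis. So do effects of elapsed time, handling or batch, which this design cannot tell apart from it.

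Changes of at least 2-fold were mostly rises, 1115 against 151 at 24h. Genomic DNA could add counts to silent genes, and the rise in fragments counted to no gene feature was taken as evenly spread DNA. It would then add 3913 counts to 1325 olfactory and vomeronasal receptor genes at 24h. They gained 55.6 counts, which is 1.42% of that (upper 95% limit 2.44%). Low genes have little room to fall, yet among genes with at least 10 CPM at 0h 83.75% of the 2-fold calls were higher (67 against 13, 95% interval 74.2% to 90.3%). DESeq2 size factors hardly moved the scale and test little (87.7% higher). The GC and length correction that centres the mean gene gave 906 against 254, 78.1% higher (95% interval 75.6% to 80.4%). The intervals of these shares treat called genes as independent and may be too narrow. Centring the mean gene lowers this share by its construction where large changes are mostly rises, so the drop does not show a scaling error. Whether scaling accounts for part of the excess stays open. The correction placed the median gene at -0.13, small beside a 2-fold change. It cannot say whether a larger scaling error accounts for the excess. An excess of activation by KLF4 or by what followed it stays open as a hypothesis, and was not tested. So do effects of doxycycline, elapsed time, handling or batch, which this design cannot tell apart from it.

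Several markers of T and NK cells were higher at 24h, although the list was not called (5 of 7 members higher and 0 lower, camera adjusted p = 0.20). Nkg7, a cytotoxic granule gene, went from 208 counts over the 0h libraries to 585 over the 24h libraries, and Lck rose by 0.51 ± 0.13 on the log2 scale. T or NK cells would bring their abundant transcripts, but 11 T cell receptor, CD3, granzyme and NK receptor genes together held 8 counts at 24h, 2.35% of the 340.3 counts Nkg7 gained beyond its 0h counts scaled to the 24h total (upper 95% limit 4.63%). Cd3e, Cd3g, Gzma, Gzmb and Ncr1 had 0 counts in all 8 libraries, which argues against such cells. The purity of the sort on GFP was not tested here. Expression in the leukaemia cells themselves stays open as a hypothesis.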

How the results depend on the processing

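Both GC and length corrections and thinning were chosen after seeing the data, and the cause of the shifts below was not tested unless stated. DESeq2 called 1668 genes at 6h, 1632 at 12h against 6h, 445 at 24h against 12h, and 1456 the same way at all 3 times. The test against a fold of 1.5 asks for larger changes. It called 213, 600, 953, 85 and 41 genes in the 5 comparisons, and the later Klf4 changes of -0.43 and -0.53 did not pass it. The GC and length correction that centres the mean gene placed the median of all genes at -0.12 at 12h and -0.13 at 24h. It called 4025 genes at 6h and 3474 the same way at all 3 times. An estimated correlation, taken from the data for each list in place of the preset 0.01, left 4, 4, 3, 3 and 2 lists. The test fry, which does not set a list against other genes, called 27 at 12h and 31 at 24h. Leaving out 1 library leaves fewer samples, and the lone one is assumed to vary like the other groups. It gave 1319 to 2715 genes at 6h, 4627 to 6627 at 12h, 5722 to 7589 at 24h, 1296 to 3061 at 12h against 6h, and 373 to 1256 at 24h against 12h. Over the time course it gave 6313 to 7825, and 1156 to 2254 the same way at all 3 times. Counts moved by over 1.5 times at 6h without 0h replicate 1 (1702) or 2 (1319), the latter also for the same way at all 3 times (1156). So did 12h against 6h without 12h replicate 1 (1853) or 2 (1296), and 24h against 12h without 12h replicate 1 (373) or 2 (386) or 24h replicate 2 (449). Klf4 stayed from 5.09 to 5.80, 4.67 to 5.37, 4.13 to 4.83, -0.45 to -0.40 and -0.56 to -0.51 on the log2 scale. Lists called ranged from 13 to 15, 15 to 19, 15 to 16, 15 to 19 and 10 to 15. Cytosolic ribosomal proteins at 12h against 6h turned upward without 6h replicate 2 (adjusted p = 0.071), and p was 8.31e-13 downward without 6h replicate 1 and at most 0.77 over the alternatives. With a replicate block 2495, 6116, 7160, 2812 and 836 genes were called, 80 of 80 list calls held, and 653 of 660 results of named genes kept their call. Deviations of same-numbered libraries correlated at 0.19, -0.02, -0.01, -0.08, -0.17 and -0.12 across genes, with mixed signs. No pairing by number common to all times showed, but this check cannot exclude one. DESeq2 size factors, no filter or a stricter one, the fits of 4 libraries, thinning and the GC and length correction that keeps the level left each total of called genes within 1.5 times. Counts of 2-fold changes moved by more, with a stricter filter to 371 rises and 42 falls at 24h. Of 660 results of named genes 0 were called in the other direction under these settings, and 656 kept their call with DESeq2 size factors, 653 with no filter, and 604 of 651 with DESeq2. Against a fold of 1.5, 163 of 660 kept it. These results are called genes and list members picked for large changes or small adjusted p, so they say little of other calls. Depth limits what 0 counts show to 0.115 to 0.147 CPM, depending on the library.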

Other observations

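Genes with almost no counts at 0h came up at later times, and those named here were chosen after their values were seen. Of 177 tested genes with at most 3 counts over both 0h libraries, 12 were called higher and reached at least 1 CPM at 6h, 32 at 12h and 53 at 24h. These 177 passed the filter on low counts only through their counts in later libraries. The numbers are therefore not a share of all genes near silence at 0h, since those that stayed silent were not tested. Bglap2, a gene of the bone protein osteocalcin, had 0 counts at 0h and reached 0.743 CPM at 6h, 3.48 at 12h and 12.9 ± 1.20 at 24h (SD, n = 2). Sod3, the gene of extracellular superoxide dismutase, also had 0 counts at 0h and reached 1.44, 4.84 and 8.09 ± 0.708 CPM. Spib, an ETS transcription factor gene, had 3 counts at 0h and 4.92 ± 0.528 CPM at 24h. The fibronectin gene Fn1 had 2 counts at 0h and 2.40 ± 0.0285 CPM at 24h. Tmem151a and the synaptic scaffold gene Shank3, with 2 counts each at 0h, were high at 6h already. Tmem151a stood at 12.6 CPM at 6h, 7.02 at 12h and 4.36 at 24h, and Shank3 at 5.57 CPM at 6h and at 10.1 and 9.86 CPM in the 12h libraries.

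Of genes called at both 6h and 24h, 21 were called in opposite directions, and those named here were chosen after their values were seen. Among them were genes of sterol synthesis. Fdft1 stood at -0.33 at 6h and 0.50 at 24h on the log2 scale, Mvd at -0.25 and 0.39, and Msmo1 at -0.23 and 0.36. Sqle stood at -0.19 and 0.28, and Sc5d at -0.39 and 0.14. The cholesterol list as a whole was not called at 24h against 0h, with 7 of 25 members higher and 7 lower (camera adjusted p = 0.90). Its median of 0.02 changed sign with the GC and length correction that centres the mean gene, to -0.11, with 5 higher and 14 lower.

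Further lists were called in some comparisons, and members named here were chosen after their values were seen. MAPK and RAS feedback genes were called at 12h (8 of 21 members higher and 4 lower, camera adjusted p = 0.038, and adjusted p = 0.17 with an estimated correlation), although their median was -0.02, and 7 were higher and 8 lower with the GC and length correction that centres the mean gene. Rasgrp2 rose by 0.86 ± 0.04 on the log2 scale (SE) and Etv5 fell by 0.92 ± 0.14. The camera adjusted p ranged from 0.028 to 0.25 over the alternatives, and the call was lost with no filter on low counts (0.25) and without 0h replicate 1 (0.062). The list was also called from 6h to 12h (5 of 21 members higher and 1 lower, camera adjusted p = 0.00021, and adjusted p = 0.054 with an estimated correlation), with a camera range of 6.5e-05 to 0.081, and not with no filter (0.081), and 5 were higher and 4 lower with the mean gene centred. TGF-beta and SMAD targets were called higher at 6h (6 of 21 members higher and 0 lower, camera adjusted p = 0.0077, and adjusted p = 0.18 with an estimated correlation) and at 12h (8 of 21 members higher and 2 lower, camera adjusted p = 0.018, and adjusted p = 0.17 with an estimated correlation), or 4 and 2 and then 7 and 3 with the mean gene centred, with Tgfbi at 1.81 ± 0.34 and Id3 at 2.23 ± 0.42 at 6h. Mitochondrially encoded genes were called higher at 6h (3 of 13 members higher and 1 lower, camera adjusted p = 0.029, and adjusted p = 0.43 with an estimated correlation), with mt-Nd2 at 0.41 ± 0.04 and mt-Co1 at -0.20 ± 0.04. Adjusted p ranged from 0.0044 to 0.43, and the call was lost without 0h replicate 1 (0.055).

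From 6h to 12h NF-kB genes were called higher (8 of 26 members higher and 2 lower, camera adjusted p = 0.015, and adjusted p = 0.30 with an estimated correlation). Their adjusted p ranged from 0.0036 to 0.30, and the call was lost with no filter (0.11) and without 6h replicate 1 (0.16). Cell cycle inhibitors were called higher as well (9 of 26 members higher and 3 lower, camera adjusted p = 0.016, and adjusted p = 0.14 with an estimated correlation), with a camera range of 0.014 to 0.14, and not without 6h replicate 2 (0.055). With the mean gene centred 7 were higher and 6 lower. From 12h to 24h genes of megakaryocytes and platelets were called lower (0 of 9 members higher and 3 lower, camera adjusted p = 0.0055, and adjusted p = 0.20 with an estimated correlation). At 24h against 0h these 3 lists were not called. NF-kB genes went both ways (10 of 26 members higher and 6 lower, camera adjusted p = 0.23), with Nfkbiz at 2.30 ± 0.17 and Ccl9 at -0.71 ± 0.04 on the log2 scale. The medians of this list, 0.05 from 6h to 12h and 0.13 at 24h, changed sign with the GC and length correction that centres the mean gene, with 8 higher and 4 lower, and 10 and 9. Cell cycle inhibitors also went both ways (13 of 26 members higher and 7 lower, camera adjusted p = 0.23, 11 and 9 with the mean gene centred), with Gadd45a at 1.69 ± 0.09. Of the platelet genes (1 of 9 members higher and 5 lower, camera adjusted p = 0.11), Rgs18 fell by 0.64 ± 0.05 and Itga2b by 0.61 ± 0.14.

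Other lists not called at 24h were MHC and antigen presentation (2 of 19 members higher and 10 lower, camera adjusted p = 0.14), interferon response (3 of 34 members higher and 12 lower, camera adjusted p = 0.16) and lysosome and autophagy (8 of 36 members higher and 12 lower, camera adjusted p = 0.23). For lysosome and autophagy the GC and length correction that centres the mean gene gave 3 higher and 24 lower. H2-K1 fell by 0.24 ± 0.04 and Gbp3 by 0.50 ± 0.05 on the log2 scale. Of the lists of other cell types, 4 more were not called. These were B and plasma cells (1 of 6 members higher and 3 lower, camera adjusted p = 0.33), erythroid cells (2 of 8 members higher and 1 lower, camera adjusted p = 0.82), stromal and endothelial cells (2 of 6 members higher and 1 lower, camera adjusted p = 0.74) and dendritic cells (3 of 10 members higher and 3 lower, camera adjusted p = 0.90). Ighm fell by 0.78 ± 0.12, Tfrc by 0.69 ± 0.04 and Pecam1 by 0.38 ± 0.04, while Eng rose by 1.37 ± 0.13.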
